A study of Mus musculus with 6 samples.

How the data were processed

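The samples were 6 libraries of cells sorted from mouse bone marrow and labelled as LT-HSCs. Of these, 3 came from mice on control food (CD) and 3 from mice kept for 3 months on food lacking serine and glycine (SGFD). RNA came from a kit for small cell numbers and libraries from a stranded mRNA kit, per the labels' protocols. The submitters' processing notes name fastp, HISAT2 and StringTie and the builds GRCm38 and mm10, with no versions. Each deposited table holds 1 value per row and library, with rows named by gene symbol, and these values are taken as FPKM; the unit is not named in the sources used here and was inferred from the values. A table lists 21878 genes, of which 15509 are above 0 in at least 1 library. No mitochondrially encoded gene is listed, and 27 rows have dates for names, as spreadsheet programs write them, 2 of these dates standing for 2 rows each; these rows stayed in the tests and are not named.

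The inference rests on the values themselves. For 15506 genes, 99.98% of those above 0, the 6 values were whole multiples of a step per library, within 0.02 fragments, as fragments divided by a fixed gene length and the library total would be, and none of 300 genes with perturbed values passed the same search. The fragments recovered this way, fixed up to a factor per gene, gave 18567577, 18253038 and 18249724 fragments for CD replicates 1 to 3 and 18532579, 19307104 and 18211238 for SGFD replicates 1 to 3. FPKM summed to 428181, 433592 and 427769 in the CD libraries and to 475019, 464222 and 485048 in the SGFD libraries. A chi-square comparison of the recovered fragments found 2.83 to 3.86 per gene between CD replicates and 5.13 to 13.7 between SGFD replicates, above the 1 expected from counting alone, so no library was a copy of another.

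Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with a trend and robust settings, for the 10620 genes with at least 1 FPKM in at least 3 of the 6 libraries. Fold changes on this scale understate the change of low genes, and folds given as such are ratios of mean FPKM. P-values are two-sided and Benjamini-Hochberg adjusted, with a threshold of 0.05; adjusted p-values per gene come from limma. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 where at least 5 members were tested, adjusted over the 46 lists that qualified of 50 written down, and beside it with an estimated correlation and with fry. Reactome sets of 10 to 300 tested genes came from fgsea 1.28.0. Gene symbols were matched to a RefSeq table of the assembly GRCm38.p6, which gave the coordinates and matched 99.4% of tested genes, and transcript length and GC content came from GENCODE transcripts for 96.9% of them. A test on simulated data used the gene means of this comparison and a fixed dispersion shared by all genes (10600 genes, 200 of them changed). It called 100% of genes changed by 1 on the log2 scale and 91.8% of those changed by 0.5, with 6.4% false calls. It called 0 of 20 unchanged lists, but its genes were drawn independently, so it does not check lists of correlated genes.

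The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The text names, for each direction, the 10 genes with the largest fitted change among those past the threshold whose groups do not overlap and whose mean is at least 1 FPKM, up to 4 members of smallest p from each list described, and a panel of 23 genes chosen for the diet, for ferroptosis and for the stem cell state. No predicted or unnamed gene had to be skipped. Some genes that this rule picks are not reported. Other members are named to say which genes went against their list or did not pass. The alternatives were another filter (none, or 5 FPKM), pseudocounts of 0.1 and 0.01, 3 scalings between libraries, array quality weights, a variance model without trend, the replicate number as a block, leaving out each library, other thresholds and protein-coding genes only. Tests made for counts were not run as planned, since the values are not counts. Y-linked genes were measured in all 6 libraries; Kdm5d fell from 8.27 ± 0.557 to 5.36 ± 0.291 FPKM and Uty from 3.54 ± 0.368 to 2.44 ± 0.156 FPKM with SGFD, while Ddx3y and Eif2s3y did not pass, and a different share of male cells was not tested.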

Results

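Gene expression was measured by RNA sequencing in cells sorted from mouse bone marrow and labelled as long-term hematopoietic stem cells (LT-HSCs). LT-HSCs are the rare bone marrow cells that can rebuild the blood for life. The gate was negative for lineage antigens, CD34 and CD135 (the protein product of Flt3) and positive for Kit and Sca1. The mice had eaten either a control diet (CD) or a diet without serine and glycine (SGFD) for 3 months, and each diet had 3 libraries. The comparison asks how the transcriptome of the sorted cells differs when these amino acids are missing from food. Serine and glycine are building blocks of one-carbon units, glutathione, purines and heme. The labels give 3 samples per diet without saying whether each came from its own mouse or from a pool, so p-values measure the spread between these samples, which could be partly technical. Whole fragments were recovered from the deposited FPKM values (fragments per kilobase of gene, scaled to the library total), up to an unknown factor per gene. They came to between 18211238 and 19307104 per library, from genes that held 97.1% to 97.4% of FPKM. Between 13781 and 14106 genes per library were above 0.

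Elane, Mpo, Ms4a3 and Ccr2, genes of granulocytes, monocytes or their progenitors, were several times higher with SGFD than with CD, and Hlf, Mycn and Procr, genes of LT-HSCs, were lower. Elane (neutrophil elastase) rose from 44.8 ± 1.14 to 344 ± 13.1 FPKM (SD, n = 3 each), and the monocyte chemokine receptor gene Ccr2 rose from 1.83 ± 0.228 to 15.4 ± 1.28 FPKM. Hlf, a transcription factor of the stem cell state, fell from 56.2 ± 0.759 to 21.9 ± 0.779 FPKM. The 10 largest rises among genes whose 3 SGFD values all lay above the 3 CD values were Hp, Ms4a3, Atf3, Lcn2, Elane, Ly6c2, Igsf6, Ccr2, Mt1 and F13a1. Haptoglobin (Hp) went from 4.23 ± 0.72 to 65.4 ± 6.07 FPKM, 15.5-fold (limma, adjusted p = 2.68e-09), and Ms4a3, a gene of granulocyte-monocyte progenitors, went from 9.64 ± 0.764 to 118.5 ± 6.43 FPKM, 12.3-fold. The 10 largest falls were Gimap7, Car1, Mycn, Hmga2, Hmox1, Slc35d3, Ddx4, Igll1, Slc16a11 and Txnip. Gimap7, a GTPase gene of lymphoid cells, fell from 7.80 ± 1 to 1.30 ± 0.1 FPKM, and Txnip, which encodes a thioredoxin-binding protein that limits glucose uptake, fell from 175.3 ± 0.272 to 63.2 ± 2.54 FPKM. In the mouse genome GRCm38, Elane lies on chromosome 10 from 79886312 to 79888216, Mpo on chromosome 11 from 87793784 to 87804412 and Hlf on chromosome 11 from 90336535 to 90390917.

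Of 10620 genes tested with limma, 6313 passed an adjusted p of 0.05, 1875 of them higher and 4438 lower with SGFD. The 3 values of one diet lay wholly on one side of those of the other diet for 65.2% of the tested genes, against 10% by chance. Most changes were small: 103 genes rose and 68 fell by at least 1 on the log2 scale of FPKM + 1. The first principal component held 82.2% of the variance and separated the diets. The second, with 7.25%, separated SGFD replicate 2, at 10.8, from SGFD replicate 3, at -8.90. The median log2 fold change of all tested genes was -0.13, so a gene at 0 stood above the typical gene. After scaling the libraries by their median ratio, that median was -0.01 and the changed genes split into 3054 higher and 2844 lower, 51.8% higher in place of 29.7%; after quantile normalization 47.0% of the changed genes were higher.

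**Figure D1:**
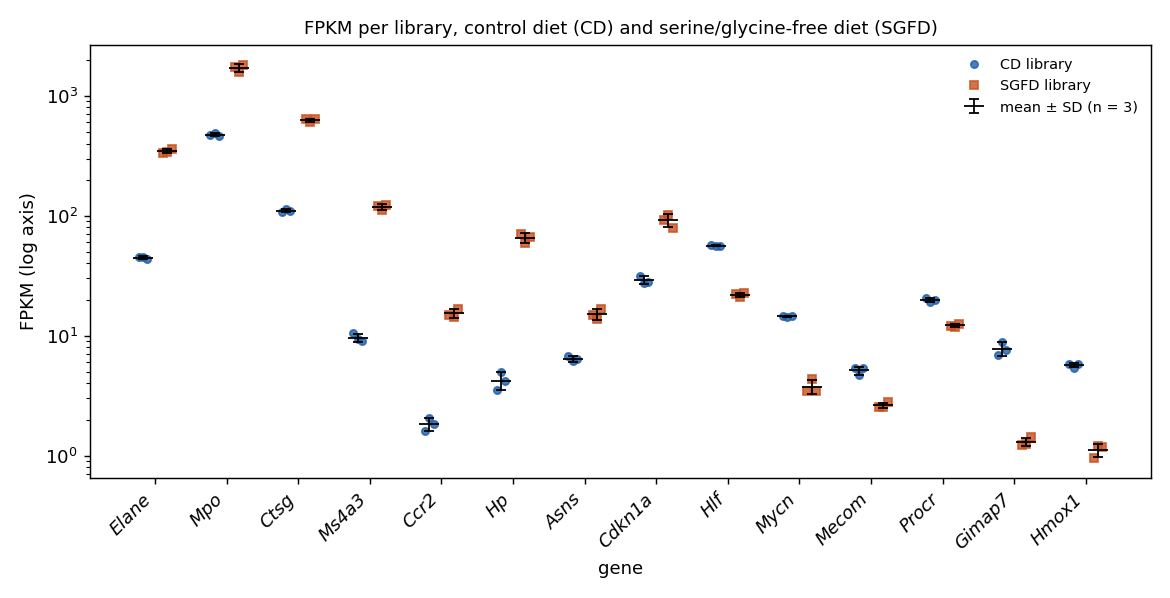
FPKM (log axis) of 14 genes in each of the 6 libraries, circles for CD and squares for SGFD, with the mean and SD (n = 3) in black. Elane was at 44.8 FPKM with CD and 344 with SGFD, Hlf at 56.2 with CD and 21.9 with SGFD, and in each gene drawn the diets did not overlap.

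Gatm, which transfers the amidino group of arginine to glycine, rose from 20.9 ± 0.764 to 41.5 ± 0.302 FPKM. The mitochondrial serine hydroxymethyltransferase gene Shmt2 rose from 85.9 ± 5.2 to 125 ± 1.71 FPKM, a log2 fold change of 0.54 ± 0.05 (SE). All 3 enzymes of serine synthesis from 3-phosphoglycerate rose: Phgdh from 206 ± 4.46 to 255 ± 15.5 FPKM, Psat1 from 72.6 ± 2.98 to 94.8 ± 6.24 FPKM and Psph from 8.14 ± 0.443 to 10.2 ± 0.96 FPKM. The cytosolic Shmt1 moved least, from 35.3 ± 1.3 to 40.0 ± 2.48 FPKM (limma, adjusted p = 0.02), and lost its call without CD replicate 2 (0.0754), CD replicate 3 (0.0555), SGFD replicate 2 (0.0505) or SGFD replicate 3 (0.0578). Phgdh did not pass after quantile normalization, with a log2 fold change of 0.065. In the list of serine and glycine enzymes 7 of 12 tested genes rose and 1, Srr, fell, though not after quantile normalization (0.129); adjusted over the list alone, 8 rose and 1 fell. Camera placed the list above other genes at an adjusted p of 0.000359, which became adjusted p = 0.149 with an estimated correlation. In the folate one-carbon list 8 of 20 genes rose and 3 fell, also when adjusted over the list alone. Mthfd2, the mitochondrial methylene-folate dehydrogenase, rose from 11.8 ± 0.258 to 17.7 ± 1.65 FPKM, and Mthfd1l and Gart rose as well. Mtr and Mtrr, which serve methionine synthesis, fell; after quantile normalization Mtrr (0.161) did not pass. Camera gave this list an adjusted p of 0.0123, and adjusted p = 0.149 with an estimated correlation.

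Of 26 tested genes of the ATF4 amino acid response, 16 rose and 2, Cebpg and Xpot, fell, with the same counts adjusted over the list alone; after median-ratio scaling neither of the 2 passed (0.309 and 0.427). Asns, which makes asparagine and is a standard readout of ATF4, rose from 6.45 ± 0.359 to 15.1 ± 1.56 FPKM, and Cebpb rose from 36.6 ± 2.16 to 71.5 ± 8.35 FPKM. Atf3 rose from 4.12 ± 1.06 to 51.2 ± 9.08 FPKM and is also a member of the immediate early list. Atf4 mRNA itself went from 110 ± 4.25 to 135 ± 21.3 FPKM (limma, adjusted p = 0.0199), a call lost without CD replicate 1 (0.054) or CD replicate 2 (0.0795) and after quantile normalization (0.373). Trib3, Ddit3 and Sesn2, other ATF4 targets, did not pass the threshold, though Ddit3 did after quantile normalization (0.0173). The list stood above other genes with an adjusted p of 9.97e-07 in camera, and adjusted p = 0.0622 with an estimated correlation. Chac1 and Slc7a11, which belong to the same response, were below the filter, at 0.227 ± 0.158 and 0.0859 ± 0.0208 FPKM with SGFD. Of 20 cytosolic tRNA synthetase genes 14 rose and none fell, Lars, Qars, Nars and Kars first, at a camera adjusted p of 3.15e-06 and adjusted p = 0.185 with an estimated correlation. Of 8 tested carriers of serine or glycine 3 fell and none rose, Slc38a1 going from 33.2 ± 1.37 to 25.2 ± 0.282 FPKM, without a camera call (adjusted p of 0.343); after median-ratio scaling 1 rose and 1 fell.

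Of 12 monocyte markers 11 rose, with a median log2 fold change of 1.57: Ly6c2 from 9.63 ± 0.63 to 70.0 ± 5.82 FPKM, F13a1 from 4.41 ± 0.148 to 29.7 ± 1.34 FPKM and Ms4a6c from 14.4 ± 0.119 to 43.2 ± 1.11 FPKM. Lysozyme, the product of the abundant monocyte gene Lyz2, had 146 ± 4.13 FPKM of mRNA with CD and 136 ± 8.91 FPKM with SGFD and did not pass; after quantile normalization Lyz2 fell (log2 fold change of -0.255, adjusted p = 0.00105). The filter admitted 2 of the 12 monocyte markers through SGFD alone. Of 9 tested neutrophil markers 8 rose, among them Lcn2 from 0.288 ± 0.126 to 12.2 ± 0.304 FPKM, and 1, Padi4, fell. Lcn2, Camp, Ifitm6 and Cxcr2 were under 1 FPKM in every CD library, so the filter admitted these 4 through SGFD alone, and without any 1 SGFD library 4 of 5 tested neutrophil markers rose; without the filter 12 of 18 rose and 1 fell. The calcium-binding proteins of mature neutrophils stayed low, S100a8 at 4.81 ± 0.913 FPKM with CD and 10 ± 0.534 FPKM with SGFD. Hdc, Mcpt8, Prg2 and Fcer1a, genes of basophils, mast cells or eosinophils, all rose, 4 of 6 tested. These 3 lists had camera adjusted p of 1.73e-11, 1.61e-05 and 0.00109, and with an estimated correlation adjusted p = 0.0622, adjusted p = 0.0805 and adjusted p = 0.212. Of 8 macrophage markers 7 fell, with C1qb going from 2.30 ± 0.328 to 0.243 ± 0.0834 FPKM (camera adjusted p of 0.00786, and adjusted p = 0.149 with an estimated correlation). The filter admitted 6 of these 8 through CD alone, and without any 1 CD library too few were left to test the list; without the filter 11 of 14 fell and none rose (camera adjusted p of 0.000835). B cell markers fell in 5 of 6 cases and erythroid markers in 5 of 7, without a camera call for either list (adjusted p of 0.0874 and 0.132); both lists were called down after median-ratio scaling, each at an adjusted p of 0.0419, and without the filter on low values (0.00701 and 0.003). The filter admitted 2 of the 6 B cell markers, Cd79a and Igll1, through CD alone. Car1 and Car2, carbonic anhydrases of erythroid progenitors, were among the erythroid genes that fell.

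Genes of progenitors that the gate excludes were split: 10 of 21 rose and 11 fell, their median log2 fold change was -0.13 and their mean 0.36, and camera called the list up at an adjusted p of 0.0356 (adjusted p = 0.149 with an estimated correlation). Median-ratio scaling and quantile normalization ended that call, at adjusted p of 0.144 and 0.492. Ctsg rose from 110.5 ± 4.03 to 627 ± 19.7 FPKM, Prtn3 from 238 ± 6.67 to 840 ± 41.6 FPKM and Mpo from 475 ± 12 to 1712 ± 121 FPKM. The mRNAs of both antigens the gate selects against were abundant in every library, and whether the sorted cells are LT-HSCs as labelled was not tested here. Cd34 had 471 ± 15.4 FPKM with CD and 429 ± 8.58 FPKM with SGFD, and the CD mean exceeded that of 98.9% of tested genes. Flt3 had 114 ± 1.19 and 90.5 ± 3.72 FPKM, at the 95.2% mark. Flt3 fell (limma, adjusted p = 0.000119); Cd34 passed at an adjusted p of 0.0125 but not after median-ratio scaling, where its log2 fold change was 0.01, nor without CD replicate 2 (0.0692) or with the replicate number as a block (0.0539). Cd48, a surface protein that LT-HSCs lack, rose from 67.9 ± 1.19 to 87.0 ± 1.01 FPKM. Its mRNA was abundant with CD already, where its mean exceeded that of 90.8% of tested genes. The CD mean of Mpo was at the 99% mark.

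LT-HSC genes fell together. Of 31 tested members 25 fell and 3 rose, with a median log2 fold change of -0.53, and the counts adjusted over the list alone were also 25 and 3. Besides Hlf, Mycn fell from 14.5 ± 0.143 to 3.75 ± 0.52 FPKM, Procr, the protein C receptor used to purify LT-HSCs, from 19.9 ± 0.827 to 12.2 ± 0.42 FPKM, and Mecom from 5.13 ± 0.397 to 2.63 ± 0.124 FPKM. Ifitm1 was the strongest exception, rising from 274 ± 8.34 to 574 ± 37.3 FPKM. Camera gave an adjusted p of 6.74e-05, and adjusted p = 0.149 with an estimated correlation. The monocyte, neutrophil and basophil markers rose in the same libraries. Of 21 tested genes reported higher in aged HSCs, 9 rose and 4 fell (camera adjusted p of 0.000105, and adjusted p = 0.0805 with an estimated correlation). Mt1, Selp, Gda and Dhx40 led the rises, with Selp (P-selectin) going from 9.61 ± 0.498 to 20.5 ± 0.414 FPKM, whereas Vwf had a log2 fold change of 0.00 ± 0.10 (SE), and 0.267 after quantile normalization (adjusted p = 0.0431).

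Quiescence regulators went both ways, 8 of 28 up and 16 down, without a camera call (adjusted p of 0.94). Cdkn1a, the cell cycle inhibitor p21, rose from 29.1 ± 2.25 to 91.5 ± 11.3 FPKM and Btg2 rose from 40.2 ± 1.09 to 91.2 ± 5.07 FPKM, while the inhibitor gene Cdkn1c went from 4.44 ± 0.511 to 3.29 ± 0.645 FPKM (limma, adjusted p = 0.0256); the call for Cdkn1c was lost without CD replicate 1 (0.0847), CD replicate 2 (0.0819), SGFD replicate 1 (0.0735) or SGFD replicate 2 (0.08) and after median-ratio scaling (0.117), quantile normalization (0.65) or the replicate number as a block (0.0536). Foxo3, Smad3 and Tsc1 fell. Of 46 G1/S genes 12 rose and 6 fell, or 9 and 5 adjusted over the list alone, and of 55 G2/M genes 23 rose and 8 fell. Ccne1 (cyclin E1) rose from 4.34 ± 0.22 to 7.79 ± 0.653 FPKM and Aurkb from 39.7 ± 1.4 to 54.8 ± 2.15 FPKM. The proliferation marker Mki67 went the other way, from 71.9 ± 1.46 to 61.5 ± 2.25 FPKM, a fall that did not pass after median-ratio scaling (0.124). The camera calls of both cell cycle lists, at adjusted p of 0.0154 and 0.00092, were lost after quantile normalization and with an estimated correlation (adjusted p = 0.149 and adjusted p = 0.325). Targets of p53 had 6 rises and 8 falls in 25 and no camera call (adjusted p of 0.29); Pmaip1, the BH3 protein Noxa, rose from 1.21 ± 0.121 to 8.30 ± 1.77 FPKM and Sesn1 fell from 28.0 ± 0.965 to 14.8 ± 1.54 FPKM.

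Genes of ferroptosis, an iron-dependent cell death through lipid peroxidation, changed in both directions. So did the tested genes as a whole, with 1875 of 10620 higher and 4438 lower. Of 24 suppressors 6 rose and 7 fell, with a median log2 fold change of -0.01 and no camera call (adjusted p of 0.311). Gpx4, the lipid peroxide reductase, rose from 99.9 ± 4.27 to 123 ± 6.46 FPKM and ferritin heavy chain (Fth1) from 914 ± 21.9 to 1070 ± 36.7 FPKM, though Fth1 fell by 0.12 on the log2 scale after quantile normalization. Scd2, a fatty acid desaturase, fell from 102.4 ± 2.15 to 67.8 ± 1.33 FPKM. Of 17 promoters or induced genes 4 rose and 6 fell, again without a call (adjusted p of 0.371, median -0.06, mean 0.07). The transferrin receptor gene Tfrc rose from 19.2 ± 1.52 to 40.6 ± 4.37 FPKM and Ptgs2 from 3.72 ± 0.703 to 12.9 ± 2.56 FPKM. Acsl4, which loads membranes with polyunsaturated fatty acids, went from 9.32 ± 0.382 to 7.05 ± 0.965 FPKM (limma, adjusted p = 0.0055), which did not pass after quantile normalization (0.161). Hmox1, heme oxygenase 1, fell from 5.69 ± 0.237 to 1.11 ± 0.136 FPKM, and the iron exporter gene Slc40a1 fell from 1.65 ± 0.247 to 0.682 ± 0.166 FPKM; both are abundant in macrophages, whose markers C1qa, C1qb and C1qc fell in the same libraries. Of 25 glutathione and NRF2 genes 14 rose and 7 fell (camera adjusted p of 0.000359, and adjusted p = 0.149 with an estimated correlation), with Gsto1, G6pdx and Gstm1 among the rises; after quantile normalization the list had an adjusted p of 0.0502.

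All 80 tested cytosolic ribosomal protein genes rose, with a median log2 fold change of 0.30, or 0.43 above the median gene; Rpl41 went from 2205 ± 33 to 3068 ± 181 FPKM. After median-ratio scaling all 80 were still higher, with a median of 0.441, but quantile normalization took this away: the list's median was then -0.01, with 16 genes higher and 14 lower. Of 76 nuclear genes of the respiratory chain 67 rose and none fell, or 70 adjusted over the list alone, with a median of 0.29; Uqcrq rose from 36.2 ± 1.02 to 61.9 ± 1.81 FPKM and Atp5g3 from 231 ± 1.68 to 316 ± 10.8 FPKM. After quantile normalization 48 of the 76 respiratory chain genes were higher, with a median of 0.148. Mitochondrial ribosomal proteins rose in 43 of 76 cases and citrate cycle enzymes in 13 of 23, with no falls in either list. Camera adjusted p was 2.61e-31 for ribosomal proteins, 3.87e-27 for the respiratory chain, 2.19e-13 for mitochondrial ribosomes and 3.01e-07 for the citrate cycle; with an estimated correlation it was adjusted p = 0.214 for the first and adjusted p = 0.149 for the other 3 lists. Glycolysis genes rose in 12 of 22 cases and fell in 4, Ldha going from 286 ± 11.6 to 437 ± 29.7 FPKM (camera adjusted p of 0.00019, and adjusted p = 0.149 with an estimated correlation). The log2 fold change was lower for genes with longer annotated transcripts. With genes in 10 bins of transcript length, the median log2 fold change was 0.00 in the shortest bin (median 629 bases), and in the longest (median 5982 bases) it was -0.36, with 38 genes higher and 765 lower.

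**Figure D2:**
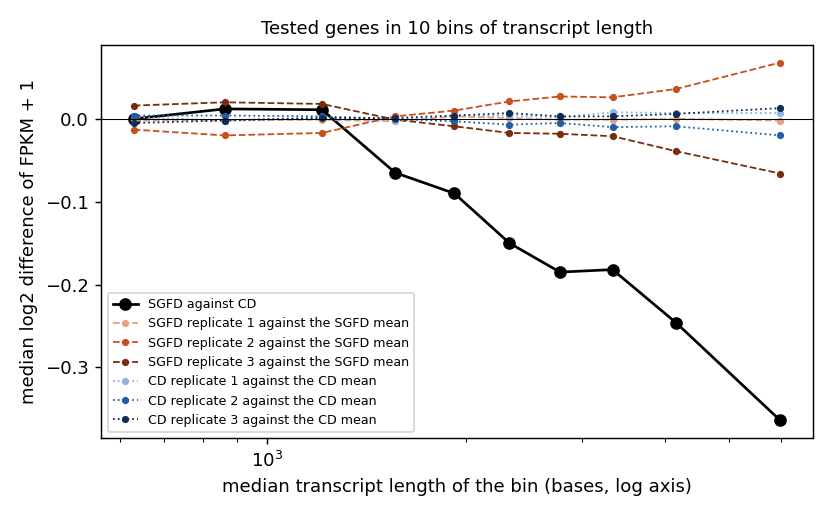
Median log2 difference of FPKM + 1 in 10 bins of transcript length (log axis, bases): SGFD against CD in black, and each library against the mean of its own diet in colour. The longest bin lay at -0.36 between the diets, at 0.07 for SGFD replicate 2 and at -0.07 for SGFD replicate 3.

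Immediate early genes were among the strongest groups. Of 28 tested 25 rose and 2, Myc and Dusp2, fell, with a median log2 fold change of 0.86. Klf2 rose from 45.4 ± 5.52 to 257.6 ± 10.2 FPKM, Klf6 from 77.6 ± 5.16 to 231 ± 23.3 FPKM and Socs3 from 30.6 ± 0.909 to 83.4 ± 8.07 FPKM. The inducible heat shock genes Hspa1a and Hspa1b rose, Hspa1a from 7.85 ± 0.432 to 41.6 ± 3.9 FPKM, while Hsph1 and Hspa4l fell. Such genes also respond to the handling of tissue before sorting. Of 18 heat shock genes 7 rose and 5 fell, and their camera adjusted p of 0.0429 became 0.0511 with the replicate number as a block, 0.0684 without CD replicate 1, 0.167 without the filter and 0.114 with the stricter minimum; after quantile normalization 5 rose and 11 fell (0.147). For immediate early genes camera gave an adjusted p of 3.01e-19, and adjusted p = 0.149 with an estimated correlation, the value that heat shock genes had as well. NF-kB and inflammatory genes rose in 10 of 23 cases and fell in 4, Tnfaip3 going from 12.4 ± 0.619 to 53.6 ± 11.2 FPKM and Cxcl2 from 6.02 ± 0.921 to 27.2 ± 6.19 FPKM (camera adjusted p of 0.000188, and adjusted p = 0.385 with an estimated correlation). Interferon-stimulated genes went down: 27 of 41 fell and 3 rose, with a median of -0.37. Irgm2 fell from 11 ± 0.551 to 4.49 ± 0.274 FPKM, whereas Gbp3 rose (camera adjusted p of 0.00489, and adjusted p = 0.149 with an estimated correlation). Of 24 genes of the unfolded protein response 14 rose and 1, Ern1, fell, the chaperone gene Calr going from 664 ± 8.27 to 962 ± 21.2 FPKM (camera adjusted p of 2.03e-06, and adjusted p = 0.0622 with an estimated correlation).

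**Figure D3:**
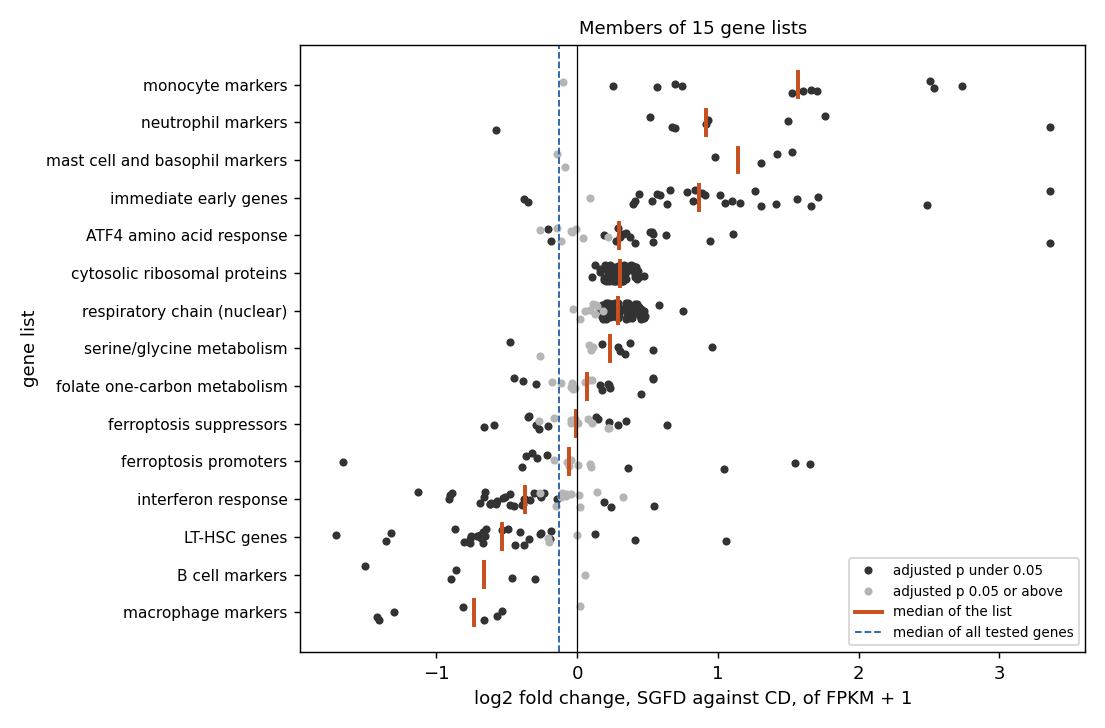
Log2 fold change (SGFD against CD, FPKM + 1) of the tested members of 15 gene lists, dark where the adjusted p was under 0.05, with each list's median in orange and the median of all tested genes, -0.13, as a dashed line. The monocyte markers had a median of 1.57, the LT-HSC genes -0.53 and the macrophage markers -0.735.

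Over the 46 lists tested, camera called 25 up and 3 down, the 3 being the LT-HSC, macrophage and interferon lists. None passed with an estimated correlation, where the lowest camera adjusted p was 0.0622 and 14 lists had an unadjusted p under 0.05. The estimate was 0.837 for ribosomal proteins and 0.668 for immediate early genes. For the ATF4 and neutrophil lists it was -0.0134 and -0.0758, under the preset 0.01, so their calls were not lost to a higher correlation. The same held for other called lists, among them folate (-0.0131), G1/S (-0.00835), aged HSC (-0.0335), macrophage (-0.0638), interferon (0.00432) and unfolded protein response genes (0.0024). For all these lists, the loss of the call with an estimated correlation does not show that correlated genes had made it. Fry, which tests whether a list's genes move one way without comparing them with other genes, called 23 up and 17 down. Among 762 Reactome sets camera called 162 up, with translation sets first (127 of 144 genes of the Translation set higher), and 26 down, among them interferon gamma signaling (47 of 67 genes lower). After quantile normalization 79 sets were called up and 98 down. No Reactome set passed with an estimated correlation, where the lowest adjusted p was 0.323.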

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

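The limma-voom test on recovered fragments and the removal of trends with transcript length or GC content were chosen after the data were seen; the rest were planned. The total of 6313 changed genes stayed within 1.5 times under each alternative except the requirement of an absolute log2 fold change of at least 1, which left 171 genes, 103 higher and 68 lower. Median-ratio scaling gave 3054 higher and 2844 lower genes, quantile normalization 2552 lower, removal of the length trend 2481 lower, and removal of the GC trend 2920 higher and 2740 lower; these settings centre the libraries anew, and 4719 genes were shared between median-ratio scaling and the main analysis, all in the same direction, against 3740 of 3780 shared after quantile normalization and 4281 of 4299 after removal of the length trend. Leaving out 1 library at a time gave 5184 to 6528 changed genes, 1596 to 1922 higher and 3588 to 4606 lower. Recovered fragments tested with limma-voom gave 6252 changed genes. The number of lists called down, 3, became 5 without a filter, after median-ratio scaling and after removal of the length trend, and 17 with fry. With an estimated correlation the lists called up or down were 0 and 0, and so were the Reactome sets. Reactome sets called up and down numbered 79 and 98 after quantile normalization, 12 were down after removal of the length trend, and 392 were down with fry. With the estimated correlation, the adjusted p of the lists led with rose to 0.149 for serine and glycine enzymes, folate, respiratory chain, G1/S, LT-HSC and interferon genes, 0.0622 for the ATF4 response, 0.0805 for genes of aged HSCs, 0.325 for G2/M and 0.385 for NF-kB. The G1/S list lost its call with the stricter minimum (0.0668) and turned its direction after quantile normalization (0.965), and the G2/M list lost its call there (0.113) and with fry (0.0988). Fry, which does not compare a list with other genes, called ferroptosis suppressors down (0.036) and quiescence regulators down (0.00952). The median log2 fold change of all tested genes was -0.131. The suppressors, with a median of -0.007, stood above it, and the quiescence regulators, with -0.285, below it. Of named genes, the log2 fold change of Cd34 became 0.005 after median-ratio scaling and 0.011 after removal of the length trend, that of Mki67 became 0.074 in the latter, and that of Fth1 became -0.119 after quantile normalization. The causes were not tested. No pairing by replicate number was seen. Same-numbered libraries deviated from their group means with correlations of -0.007, -0.227 and -0.133, and no library correlated best with its own number. With the replicate block 5793 genes passed. So few libraries cannot exclude a shared day or litter, on which the labels say nothing. The count-based tests of the plan and their size factors were not run because the values are FPKM, and limma-voom on recovered fragments was added in their place. The filter left the lowest genes, such as Chac1 and Slc7a11, untested in the main analysis.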

Other observations

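The genes in this paragraph were chosen after their values were seen. All 6 tested Gimap genes, GTPases that support lymphocyte survival and lie in 1 cluster, fell, Gimap6 from 122 ± 4.11 to 48.5 ± 2.16 FPKM (SD, n = 3) and Gimap1 from 62.8 ± 1.06 to 32.0 ± 3.75 FPKM, and all 6 fell past the threshold under the 3 other scalings as well. Rag2, Il7r, Ccr9, Notch1 and Igll1 also fell under each scaling, while Dntt, at 322 ± 16.8 and 284 ± 15.3 FPKM, did not pass after median-ratio scaling. Rag2, Ccr9 and Igll1 were under 1 FPKM in every SGFD library, so the filter admitted them through CD alone. Ly6d, another gene of lymphoid progenitors, rose, from 2.57, 3.69 and 2.23 FPKM in CD replicates 1 to 3 to 3.92, 4.13 and 3.83 FPKM in SGFD replicates 1 to 3. The T and NK cell list had no camera call (adjusted p of 0.607), and its member Nkg7 rose from 104 to 133 FPKM. The MHC class II genes Cd74, H2-Aa, H2-Eb1 and H2-Ab1 fell, H2-Eb1 from 17.5 ± 0.688 to 6.53 ± 0.743 FPKM. Among lineage transcription factors, Cebpe rose from 0.981 ± 0.563 to 4.50 ± 0.901 FPKM, Cebpa from 31.1 ± 1.38 to 49.8 ± 4.3 FPKM and Irf8 from 28.6 ± 0.945 to 43.3 ± 0.616 FPKM, and Gata1 and Gata2 fell, Gata2 from 47.7 ± 0.21 to 33.7 ± 1.21 FPKM. Gfi1 was at 13.4 ± 0.8 and 12.3 ± 1.22 FPKM and did not pass. Csf1r, the macrophage colony-stimulating factor receptor, rose from 6.37 ± 0.24 to 21.4 ± 0.326 FPKM, and Csf3r, its granulocyte counterpart, fell from 42.7 ± 4.22 to 25.6 ± 1.83 FPKM.

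All tests of the next 4 paragraphs except that of GC content were chosen or given their bounds after their results were seen. Elane, Mpo, Prtn3, Ctsg and 11 of 12 monocyte markers (8 of the 9 at 1 FPKM or more in all libraries) rose while 25 of 31 LT-HSC genes fell. Mature neutrophils among the sorted cells are argued against, because S100a8 and S100a9 together gained 10.3 FPKM, 0.39% of the 2654 FPKM gained by Elane, Mpo, Prtn3 and Ctsg. A lower share of stem cells, with every other cell type raised alike, is not decided, although the markers did not rise alike. Over markers at 1 FPKM or more in all 6 libraries, the erythroid list had a median log2 fold change of -0.511. That is 2.117 ± 0.654 (SE) below the monocyte list, and the dendritic list lay 1.884 ± 0.541 (SE) below it. These errors treat the genes of a list as independent, though all were measured in the same 6 libraries. Erythroid members such as Car2, at 192 FPKM with CD, may be expressed by the sorted cells themselves. The mast cell, basophil and eosinophil list rose as well, with a median of 1.145, and 4 of its 6 members rose and 0 fell. It lay 0.461 ± 0.582 (SE) below the monocyte list. More cells of the monocyte lineage, alone or together with cells of these other types, stay open. More CD34- or FLT3-bearing progenitors within the gate stay open as well: Cd34 changed by -0.134 and Flt3 by -0.33, but both were so abundant with CD that a small added share would not show. An effect of the diet on expression within the stem cells is untested, as these bulk libraries do not separate it from a changed mix of cells.

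Immediate early genes rose with SGFD by a median of 0.86 on the log2 scale. Scaling between libraries is argued against as the reason, since the lowest median under the other scalings was 0.726 with the call kept. Handling that differed between the diets cannot be told apart from the diet, as all libraries of a diet may have been prepared together. The heat shock list, which handling would raise as well, had a median of 0.029 with a standard error of 0.215 and decides nothing. Some immediate early genes also differed within SGFD. In SGFD replicates 2 and 3, Atf3 was at 60.7 and 42.6 FPKM and Klf6 at 256 and 210 FPKM. Klf2 differed less, at 266 and 260 FPKM. Why libraries of the same diet differed was not tested.

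Ribosomal protein and respiratory chain genes rose while long genes fell. The log2 fold change and transcript length had a Spearman rho of -0.337 across genes, which are not independent replicates, and SGFD replicates 2 and 3 differed from each other along length as well, by 0.068 and -0.066 from their mean in the bin of longest transcripts. Length as the whole reason is argued against: with the trend removed, ribosomal proteins kept 70.0% and respiratory chain genes 72.3% of their distance from the median gene, so that length could account for the rest. GC content is argued against too, with 96.3% kept at least. Scaling as the whole reason for the respiratory chain genes is argued against less firmly. After quantile normalization their median was still 0.148, with 48 of 76 genes higher. The camera adjusted p of 1.65e-09 there rests on the preset correlation of 0.01, while the list's estimated correlation was 0.356. By the measure used for length and GC content, only 39.4% of the distance from the median gene was kept, so that scaling could account for the rest. For ribosomal proteins it stays open, because all 80 stayed higher after median-ratio scaling, with a median of 0.441, but their median was -0.005 after quantile normalization, which gives the most abundant genes of every library the same values. An effect of the diet on both groups is untested.

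With 3 libraries per diet there are 10 splits of the 6 libraries, so the share of splits as large as the real one cannot go below 0.1. The real split, 1 of the 10, gave 6313 changed genes in limma at the adjusted threshold against 0 at most for the other splits, 28 lists called by camera against 22, and 188 Reactome sets against 157. Camera with a preset correlation called many lists under splits that mix the diets. Every other split has libraries of both diets on each side, so the diet difference widens the spread within its groups. Its 0 changed genes therefore do not measure chance, and its list calls still hold part of the diet contrast.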
